A study of Novosphingobium sp. HR1a with 12 samples.

How the data were processed

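RNA was measured by paired-end Illumina sequencing in 12 libraries of Novosphingobium sp. HR1a, 3 replicates in each of 4 groups: wild type and pahT mutant, with glucose or phenanthrene. Groups were taken from the sample titles. Per the labels, RNA was extracted with TRIzol and libraries were made with NEBNext Ultra reagents. The labels describe growth in minimal medium for plate reader cultures and do not say that the RNA came from these. They also mention precultures with the corresponding antibiotic, so an antibiotic may have differed between genotypes, which cannot be separated from the mutation. The genome build and the annotation are not given in the sources used here.

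The authors' deposited tables number 3, each comparing 2 groups of 3 libraries. Per the labels, the authors aligned reads with HISAT2 (version written as 0.6.1), counted them with HTSeq and used DESeq2 1.20.0, whose adjusted p-values are the ones reported per gene. Each table holds, for each gene, a signal value for each group, deposited by the authors in a unit that they do not name. The signal values are pooled over the replicates and normalised within a table. They are never 0, and the smallest column total was 1.27e+06. At equal signal values the implied precision was 3.10 times that of regulators for TonB-dependent and iron receptors and 0.514 times for hypothetical proteins, as values divided by gene length would give. The authors' fold changes are in log2, the first group over the second, and differed from the log2 ratio of the signal values by at most 0.0541. The authors' p and adjusted p columns have no unit (other). Recomputing the Benjamini-Hochberg adjustment from the deposited p-values gave the deposited adjusted values within 1.66e-04. An adjusted p is missing for 0 genes in the phenanthrene table, 119 in the glucose table and 356 in the wild-type table, and these were not counted. An unnamed column and the significance column were not used here.

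Values per library were not analysed here, because the tables give 1 value per group. No own test per gene was therefore made, and the 3 comparisons are the authors'. The depth per library is unknown, and no interval based on counts can be given. A standard error was derived for each gene as the size of the log2 fold change divided by the normal quantile of its two-sided p, which assumes a Wald test. Its median was 0.119 (log2) in the phenanthrene table, 0.146 in the glucose table and 0.134 in the wild-type table. For p listed as 0 (11 genes on phenanthrene, 2 on glucose and 6 in wild type) p was taken as 1e-308, so the derived error is an upper bound there and is not printed, and tests of the difference for these genes are conservative.

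Genes carry a number and a product name. A gene is written as peg and its number. The reference table of locus tags could not be paired with these numbers, so no genome position is given, and neighbours are genes with consecutive numbers. Hypothetical products make up 27.6% of the genes. The glucose table lists 1 identifier 2 times and lacks 2 genes. The repeated line is included in the count of 5999 genes and left out where tables are joined.

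The difference of the mutation effects was the log2 fold change on phenanthrene minus that on glucose, with the root of the summed squared errors, a two-sided normal test and Benjamini-Hochberg adjustment over 5998 genes. The plan made before the data were examined was to describe the tables only and to leave the interaction untested if the tables held no values per library. The test was added after the tables were seen. It was tested on simulated data of 5987 genes. It called 17 of 50 genes with a simulated difference of 0.5 (log2) and 34 of 50 with 1. It called 47 of 50 with 1.5, 47 of 50 with 2, and 6 of 5787 without one. The simulated noise was normal with the implied errors, as the test assumes, so these assumptions were not checked.

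Group values of the mutant tables were put on the scale of the wild-type table by the median ratio of the shared wild-type group, 1.07459 for phenanthrene over 6119 genes and 0.969946 for glucose over 6117 genes. The SD of these ratios was 0.000438 and 0.000430 (log2). The mutant's phenanthrene over glucose change rests on these values and has no test.

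Before the data were examined, 21 gene lists were fixed as patterns on product names. The plan allowed matches that plainly belong to another protein family to be taken out. This was done by further patterns, so the lists hold the members left after that step. The pattern of the ortho-cleavage list also holds benzoate, which matches ring-hydroxylating dioxygenases too. That of the flagella and chemotaxis list also holds pilus and pilin. That of the trehalose, glycogen and ectoine list also holds betaine, osmoprotectant, alpha-glucosidase and maltose. For each list the members past an adjusted p of 0.05 were counted over all genes and adjusted over the list alone. Lists with at least 5 members were tested with cameraPR of limma 3.58.1 (R 4.3.3) on signed normal quantiles of the p-values, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over lists. A correlation could not be estimated without values per library, so 0.05 was used as a stricter preset value. In simulated data with independent genes the test called 20 of 20 shifted lists and 1 of 390 unshifted ones. This does not check the test for lists whose genes move together. A list of stable RNA genes had no member left and was not tested.

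Genes were named by a rule fixed before the data were examined: pahT and 5 genes with neighbouring numbers on each side; for each comparison the 10 highest and 10 lowest fold changes past an adjusted p of 0.05 with a value of at least 50 in the higher group and an informative product; up to 4 genes per list and comparison; the 5 most positive and 5 most negative differences; and the 2 most abundant genes of each group. A condition on the order of replicates could not be applied. The text prints a part of these genes. The regulators next to acetyl-CoA hydrolase and the fructose repressor were added after their values were seen, as were the limits of the runs of consecutive numbers.

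Effects were compared across genes by Pearson and Spearman correlation. Where a pair of comparisons shares the same wild-type libraries, the values were set beside 100 simulations of unchanged groups. Alternatives were a mean value of at least 50, no filter, an adjusted p of 0.01, at least 2-fold changes, equal column totals, pseudocounts of 0.1, 1 and 10 on the group values, a t distribution, and in the list test other statistics and leaving out the cbb3 run. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.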

Results

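Transcripts of Novosphingobium sp. HR1a, a bacterium that can use the polycyclic aromatic hydrocarbon phenanthrene as a carbon source, were measured by RNA sequencing in 4 groups of 3 libraries. The groups were wild type and a pahT mutant, each with glucose or phenanthrene as the carbon source. The mutant was made by integrating a plasmid with a kanamycin resistance cassette through a 340 bp internal fragment of orf1998. The authors' deposited tables cover 3 comparisons: mutant over wild type on glucose, mutant over wild type on phenanthrene, and phenanthrene over glucose in wild type. Each table gives 1 pooled value per group for up to 6119 genes, with a log2 fold change, a p-value and an adjusted p. No value per library and no read count was analysed here, so the depth of each library is unknown, and errors are standard errors implied by the authors' fold changes and p-values. Nothing in the labels says that the 3 replicates of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. Genes are named by the product and number in the tables, which the files do not pair with genome positions.

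The targeted gene was examined first. The tables do not name pahT. The gene numbered peg.1998, a regulator of the IclR family, is taken as pahT because its number is that of orf1998. Its value was 606 in the mutant and 541 in wild type on glucose in the authors' deposited table, a log2 fold change of 0.16 ± 0.09 (implied SE, adjusted p = 0.120). On phenanthrene the authors' deposited table gives 759 in the mutant and 741 in wild type, a log2 fold change of 0.04 ± 0.07 (adjusted p = 0.725). Neither value was lower in the mutant. A pooled value does not show which part of the gene the reads came from, so it does not check an insertion inside the gene, and "mutant" below stands for the libraries labelled pahT mutant. In wild type, the authors' deposited table has this gene at 689 on phenanthrene and 558 on glucose, a rise of 0.31 ± 0.07 (log2, adjusted p = 2.38e-04).

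Genes with the next numbers moved in different ways. On the lower side, peg.1997, annotated as a multidrug efflux protein, was lower in the mutant on glucose (-0.65 ± 0.10) and on phenanthrene (-0.37 ± 0.07) in the authors' deposited tables. The hydrolase peg.1993 and the hydratase peg.1994, both annotated in aromatic compound breakdown, were also lower in the mutant on glucose, at -0.54 ± 0.09 and -0.60 ± 0.15 in the authors' deposited table. On phenanthrene the authors' deposited table has peg.1993 at -0.37 ± 0.06, peg.1994 at -0.33 ± 0.08 and peg.1996, a carnitine dehydratase-like protein, at -1.14 ± 0.12. On glucose peg.1996 missed the threshold in the authors' deposited table (-0.38 ± 0.19, adjusted p = 0.0978), as did the aldolase peg.1995 (-0.06 ± 0.28), which fell on phenanthrene (-0.57 ± 0.13). On the upper side, the mobile element protein peg.2000 was higher in the mutant on glucose (0.54 ± 0.17) and phenanthrene (0.37 ± 0.12) in the authors' deposited tables. The hypothetical protein peg.2003 was higher by 1.33 ± 0.28 on glucose and 0.86 ± 0.25 on phenanthrene in the same authors' deposited tables.

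The effect of the mutation on glucose was the next comparison. Genes for fructose uptake and for oxidation of alcohols by a quinoprotein dehydrogenase were far lower in the mutant on glucose. More members of the ribosomal and ring cleavage lists were called lower than higher, and these list calls were lost with a correlation of 0.05. Acetyl-CoA hydrolase, which releases acetate from acetyl-CoA, rose most. A run of 4 genes with phenylalanine-4-hydroxylase, a pair of methyltransferase genes and the trehalose, glycogen and ectoine list were also higher. The authors' deposited table has 2228 of 5999 genes past an adjusted p of 0.05, 1131 higher and 1097 lower in the mutant. Of these, 328 changed at least 2-fold, 268 higher and 60 lower, and the median size of a called change was 0.51 (log2).

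Acetyl-CoA hydrolase (peg.4899) stood at 879 in the mutant and 20.9 in wild type in the authors' deposited table, 42.2-fold higher, with p listed as 0. The genes numbered on either side of it, regulators of the LysR family (peg.4898, 0.46 ± 0.20, adjusted p = 0.0578) and the TetR family (peg.4900, 0.06 ± 0.08, adjusted p = 0.606), missed the threshold in the authors' deposited table. A run of 4 consecutive numbers (peg.2614 to peg.2617) holds phenylalanine-4-hydroxylase, which makes tyrosine, and 4-hydroxyphenylpyruvate dioxygenase, which makes homogentisate. All 4 were higher in the authors' deposited table, by a median of 2.22 (log2), or 4.66-fold, with phenylalanine-4-hydroxylase (peg.2617) at 2.28 ± 0.10 and the dioxygenase (peg.2616) at 2.25 ± 0.09. A pair of genes annotated as homocysteine methyltransferases, which make methionine, rose by 2.83 ± 0.10 (peg.2845) and 2.21 ± 0.08 (peg.2847) in the authors' deposited table, and the acetyltransferase numbered between them (peg.2846) by 2.77 ± 0.16. The glycosyltransferase peg.4485 and the cAMP-binding regulator peg.5818 were higher by 1.87 ± 0.12 and 1.90 ± 0.14 in the authors' deposited table.

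The fructose genes peg.4145 to peg.4148 were all lower in the authors' deposited table, by a median of -4.54 (log2), or 23.3-fold. They encode a protein named RpfN (peg.4145, -4.97 ± 0.27), the fructose transporter IIB component (peg.4146, -4.66, p listed as 0), 1-phosphofructokinase (peg.4147, -4.43 ± 0.16) and a phosphotransferase of the same system (peg.4148, -3.93 ± 0.11), all from the authors' deposited table. The fructose repressor gene FruR, numbered next (peg.4149), was lower by less in the authors' deposited table (-0.46 ± 0.12, adjusted p = 5.57e-04). Of the 19 genes from peg.282 to peg.300, 16 were lower in the authors' deposited table, with a median of -2.34 (log2), or 5.06-fold. Among them were the quinoprotein alcohol dehydrogenase (peg.288, -3.64 ± 0.51), cytochrome c550 (peg.291, -3.66 ± 0.53), cytochrome c2 (peg.300, -3.45 ± 0.61) and an aldehyde dehydrogenase (peg.282, -2.90 ± 0.43) in the authors' deposited table. In the same authors' deposited table the subunits of 3-oxoadipate CoA-transferase were lower by -1.92 ± 0.16 (peg.5247) and -2.05 ± 0.24 (peg.5248). The limits of these runs of numbers were drawn after the values were seen.

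Gene lists chosen by product name before the data were examined gave 6 lists past an adjusted p of 0.05 on glucose (cameraPR of limma on z values from the authors' deposited table). Genes of the trehalose, glycogen and ectoine list, whose pattern also takes other osmoprotectants and maltose, were higher in 13 of 24 and lower in 3. Adjusted over the list alone the counts were 13 and 4 (adjusted p = 1.81e-04, and adjusted p = 0.0158 with a correlation of 0.05 between genes). Examples from the authors' deposited table are trehalose-phosphate synthase (peg.2943, 1.81 ± 0.10), its phosphatase (peg.2941, 1.67 ± 0.12) and ectoine synthase (peg.5930, 1.12 ± 0.12). Ribosomal protein genes were lower, 33 of 54 against 2 higher, with the same counts adjusted over the list alone (adjusted p = 2.40e-04, and adjusted p = 0.0503 with a correlation of 0.05). Their changes were small in the authors' deposited table, with a median of -0.26 (log2). Ortho-cleavage and related genes were lower in 19 of 54 and higher in 2, or 19 and 4 adjusted over the list alone (adjusted p = 2.40e-04, and adjusted p = 0.0503 with a correlation of 0.05). Genes of the upper pathway of polycyclic aromatics were lower in 10 of 33 and higher in 2, with the same counts adjusted over the list alone (adjusted p = 0.00863, and adjusted p = 0.120 with a correlation of 0.05). The large subunit of the naphthalene and biphenyl dioxygenase (peg.1926) fell by 1.02 ± 0.10 (log2) in the authors' deposited table. Meta-cleavage genes were lower in 7 of 16 and higher in 0, with the same counts adjusted over the list alone (adjusted p = 0.0244, and adjusted p = 0.120 with a correlation of 0.05). Conjugation and type IV secretion genes were higher in 21 of 67 and lower in 4, with the same counts adjusted over the list alone (adjusted p = 0.0162, and adjusted p = 0.252 with a correlation of 0.05). Many members of that list had low values: among genes with a mean value of at least 50 its direction turned to lower (adjusted p = 0.503). The meta-cleavage call also ended among such genes (adjusted p = 0.0597) and with log2 fold changes in place of z (adjusted p = 0.0704).

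The same contrast was made on phenanthrene. The fructose and alcohol dehydrogenase genes were again far lower in the mutant, and acetyl-CoA hydrolase and the phenylalanine genes higher. Genes of the cbb3 cytochrome oxidase, a terminal oxidase with high affinity for oxygen, were far lower in the mutant on phenanthrene, and 4 of the 10 tested genes of this run were also lower on glucose (run median -0.42, log2) in the authors' deposited table. Also lower on phenanthrene were the list of flagellar genes and most called genes of the chaperone list, whose call was lost under 2 alternatives. The authors' deposited table has 2903 of 6119 genes past an adjusted p of 0.05, 1424 higher and 1479 lower. Of these, 411 changed at least 2-fold, 265 higher and 146 lower, and the median size of a called change was 0.48 (log2).

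Cytochrome c550 (peg.291) fell most, from 366 in wild type to 4.77 in the mutant in the authors' deposited table, 76.7-fold, with p listed as 0. All 19 genes from peg.282 to peg.300 were lower in the authors' deposited table, with a median of -3.97 (log2), or 15.6-fold. The quinoprotein alcohol dehydrogenase (peg.288) was lower by -5.58 and the aldehyde dehydrogenase (peg.282) by -5.06, both with p listed as 0 in the authors' deposited table, and cytochrome c2 (peg.300) by -5.40 ± 0.14. The 4 fructose genes were lower in the authors' deposited table by a median of -5.25 (log2), or 38.1-fold, and for all of them p is listed as 0. Of the 11 genes from peg.3164 to peg.3174, 10 were lower in the authors' deposited table, with a median of -2.76 (log2), or 6.77-fold. This run holds the oxidase subunits CcoN (peg.3173, -3.15 ± 0.19), CcoO (peg.3172, -3.42 ± 0.09), CcoQ (peg.3171, -3.51 ± 0.14) and CcoP (peg.3170, -3.11, p listed as 0) in the authors' deposited table. It also holds a gene for an oxygen-independent coproporphyrinogen oxidase, an enzyme of haem synthesis (peg.3164, -2.16 ± 0.25), and one for the outer membrane protein W (peg.3174, -3.47, p listed as 0), again from the authors' deposited table. The ADP-forming acetyl-CoA synthetase (peg.1512) fell from 1432 to 280.4 in the authors' deposited table (-2.35 ± 0.20). The protocatechuate 3,4-dioxygenase chains were lower in the authors' deposited table, at -2.55 ± 0.15 (peg.5157) and -1.85 ± 0.13 (peg.5158). On the scale of the wild-type table, the muconate cycloisomerase peg.5159 had 29.6 in wild type and 5.43 in the mutant. The 4-carboxymuconolactone decarboxylase peg.776 went the other way at low values, with 3.64 in wild type and 10.7 in the mutant.

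Acetyl-CoA hydrolase (peg.4899) was 33.9-fold higher in the mutant on phenanthrene, at 901 against 26.6 with p listed as 0 in the authors' deposited table. The 4 phenylalanine genes were higher by a median of 1.76 (log2), or 3.39-fold, in the authors' deposited table. A tripartite multidrug efflux system and its neighbouring TetR regulator (peg.2385 to peg.2388) were higher by a median of 1.56 (log2), or 2.94-fold, in the authors' deposited table, all 4 past the threshold. The methyltransferases peg.2845 and peg.2847 rose by 1.75 ± 0.08 and 1.91 ± 0.07, and the hook-length protein FliK (peg.5844) by 1.93 ± 0.10, in the authors' deposited table. The glycosyltransferases peg.4485 (1.95 ± 0.10) and peg.925 (1.89 ± 0.08) were higher as well in the authors' deposited table.

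On phenanthrene 6 lists passed an adjusted p of 0.05 in the same list test. Genes of the trehalose, glycogen and ectoine list were higher in 15 of 24 and lower in 2, with the same counts adjusted over the list alone (adjusted p = 6.15e-04, and adjusted p = 0.0398 with a correlation of 0.05). Genes of the flagella and chemotaxis list, whose pattern also takes pilus and pilin, were lower in 30 of 63 and higher in 7. The counts adjusted over the list alone were again the same (adjusted p = 4.19e-04, and adjusted p = 0.0480 with a correlation of 0.05). Examples from the authors' deposited table are FlaF (peg.3064, -1.24 ± 0.09), the P-ring protein FlgI (peg.3050, -1.19 ± 0.07) and the motor protein MotB (peg.3062, -1.17 ± 0.10). Ortho-cleavage genes were lower in 26 of 54 and higher in 6, with the same counts adjusted over the list alone (adjusted p = 4.19e-04, and adjusted p = 0.0480 with a correlation of 0.05). Meta-cleavage genes were lower in 9 of 16 and higher in 1, or 9 and 2 adjusted over the list alone (adjusted p = 0.00259, and adjusted p = 0.0398 with a correlation of 0.05). Catechol 2,3-dioxygenase (peg.1968), which opens the catechol ring, fell by 0.88 ± 0.06 (log2) in the authors' deposited table. Oxidative phosphorylation genes were lower in 20 of 46 and higher in 11, or 20 and 12 adjusted over the list alone (adjusted p = 4.19e-04, and adjusted p = 0.0398 with a correlation of 0.05). With ranks in place of z values that call was lost (adjusted p = 0.122), and also without the cbb3 run, which holds 4 of the 46 genes (adjusted p = 0.252). Members of the same list went up in the authors' deposited table, such as a subunit I of another cytochrome c oxidase (peg.4510, 1.12 ± 0.11) and a subunit of cytochrome o oxidase (peg.3862, 1.11 ± 0.15). Chaperone genes were lower in 17 of 30 and higher in 4, with the same counts adjusted over the list alone (adjusted p = 0.00449, and adjusted p = 0.0677 with a correlation of 0.05). ClpB (peg.2269), which resolves protein aggregates, fell by 1.42 ± 0.06 (log2) in the authors' deposited table. Among genes with a mean value of at least 50 the chaperone call was lost (adjusted p = 0.145).

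In wild type the carbon source was compared, phenanthrene over glucose. Genes of aromatic degradation and of the cbb3 oxidase were higher on phenanthrene, and genes of ribosomal proteins and both pairs of GroES and GroEL genes were lower. The authors' deposited table has 2036 of 5763 genes past an adjusted p of 0.05, 947 higher and 1089 lower on phenanthrene. At least 2-fold changes were called for 230 genes, 159 higher and 71 lower, and the median size of a called change was 0.46 (log2). The direction of small changes depends on the scaling: the authors' values sum to less on phenanthrene, and equal column totals raise every log2 fold change by 0.157 and give 1649 higher and 563 lower genes, 74.5% higher against 46.5%. Changes are given on the authors' scale, on which the median over all genes is near 0 (-0.003, log2).

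Of the 72 genes from peg.1926 to peg.1997, the block of numbers that ends beside peg.1998, 63 were higher on phenanthrene and 3 lower in the authors' deposited table, with a median of 2.14 (log2), or 4.41-fold. They include the naphthalene and biphenyl dioxygenase subunits (peg.1926, 2.68 ± 0.08, and peg.1927, 2.77 ± 0.08), catechol 2,3-dioxygenase (peg.1968, 2.36 ± 0.08) and a toluate and benzoate dioxygenase subunit (peg.1979, 2.51 ± 0.09) in the authors' deposited table. The tripartite efflux gene peg.1942, which has a number inside this block, was lower in the authors' deposited table (-0.88 ± 0.08). In the mutant, 58 of these 72 genes were lower than in wild type on phenanthrene and 7 higher, with a median of -0.59 (log2), and 45 were lower and 6 higher on glucose, with a median of -0.53, in the authors' deposited tables.

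**Figure D1:**
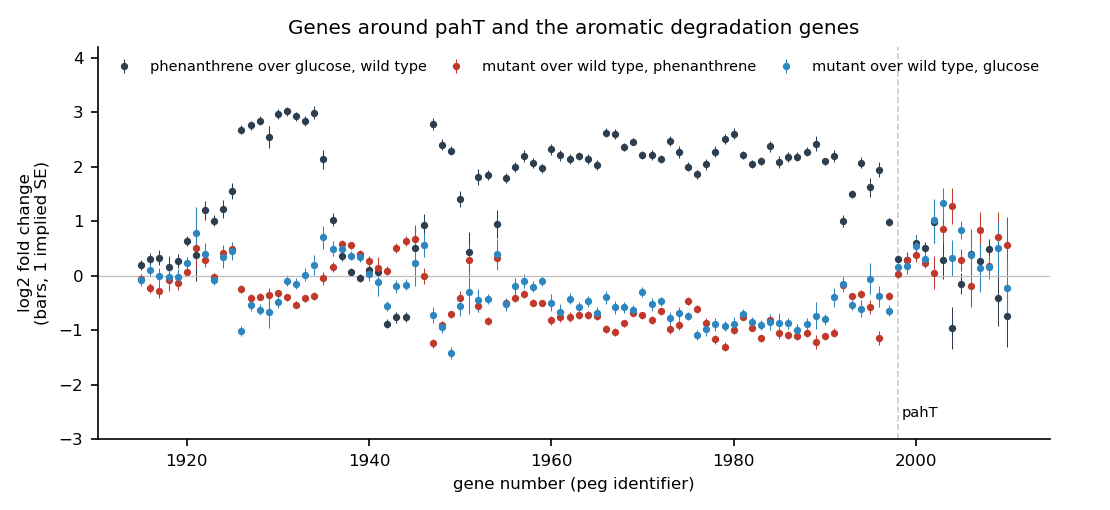
Log2 fold changes in the authors' deposited tables (vertical axis, bars of 1 implied SE) of genes in order of their number (horizontal axis), for phenanthrene over glucose in wild type and for the mutant over wild type on each carbon source. From peg.1926 to peg.1997 the carbon source effect has a median of 2.14, the mutation effects have medians of -0.53 on glucose and -0.59 on phenanthrene, and pahT is marked by a dashed line.

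The cbb3 oxidase genes rose most in wild type on phenanthrene. All 10 tested genes from peg.3164 to peg.3174 were higher in the authors' deposited table, with a median of 4.04 (log2), or 16.5-fold. CcoO (peg.3172) went from 97.4 on glucose to 1567 on phenanthrene and CcoP (peg.3170) from 73.9 to 1243, with p listed as 0 in the authors' deposited table. Outer membrane protein W (peg.3174) rose by 2.72 ± 0.09 (log2) in the authors' deposited table. The alcohol dehydrogenase genes were higher on phenanthrene in 15 of 19 cases (2.30-fold at the median) and the fructose genes in 4 of 4 (1.76-fold) in the authors' deposited table. Among the genes that fell, the ferrichrome receptor peg.4889 was lower by -2.89 ± 0.12 in the authors' deposited table, and the nickel transporter component NikK (peg.4235) by -1.92 ± 0.12. GroEL (peg.5695) fell from 1050 to 223 and GroES (peg.5696) from 1395 to 305 in the authors' deposited table, both chaperonin proteins. The subunits of 3-oxoadipate CoA-transferase (peg.5247, -1.39 ± 0.15, and peg.5248, -1.13 ± 0.15) were lower on phenanthrene in the authors' deposited table.

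In the list test 11 lists passed an adjusted p of 0.05 in wild type. Ribosomal protein genes were lower in 51 of 54 and higher in 0, with the same counts adjusted over the list alone (adjusted p = 2.71e-20, and adjusted p = 5.61e-09 with a correlation of 0.05), with a median of -0.62 (log2) and 49 lower under equal totals. Meta-cleavage genes were higher in 8 of 16 and lower in 1 (adjusted p = 2.53e-17, and adjusted p = 2.76e-11 with a correlation of 0.05). Upper pathway genes were higher in 13 of 33 and lower in 2 (adjusted p = 1.81e-09, and adjusted p = 4.47e-05 with a correlation of 0.05). Ortho-cleavage genes were higher in 14 of 53 and lower in 7 (adjusted p = 1.21e-05, and adjusted p = 0.00930 with a correlation of 0.05), a call lost with ranks (adjusted p = 0.125). For these 3 lists the counts adjusted over the list alone were the same. The pattern of the ortho-cleavage list includes benzoate, so it also matches ring-hydroxylating dioxygenases of the aromatic block, such as peg.1979 (2.51, log2). Subunits of 3-oxoadipate CoA-transferase fell (peg.5247, -1.39, and peg.5248, -1.13). The call therefore does not show that ortho cleavage rose as a pathway. Iron uptake genes were lower in 16 of 41 and higher in 5, the same adjusted over the list alone (adjusted p = 3.27e-05, and adjusted p = 0.00930 with a correlation of 0.05), a call lost among genes with a mean value of at least 50 (adjusted p = 0.211). Ferrichrome receptors were among them in the authors' deposited table (peg.4234, -2.34 ± 0.13, and peg.3535, -2.07 ± 0.22), while bacterioferritin, which stores iron (peg.5772), rose by 1.23 ± 0.12.

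Central metabolism, which the series names as its subject, moved by smaller amounts at the list medians, with large rises of single genes in the aromatic block. Genes of glucose uptake, the Entner-Doudoroff pathway, glycolysis and the pentose phosphate pathway were lower on phenanthrene in 15 of 32 and higher in 0, or 16 and 0 adjusted over the list alone (adjusted p = 0.00386, and adjusted p = 0.0626 with a correlation of 0.05). Under equal totals 9 were lower and 1 higher, and the list median went from -0.23 to -0.07 (log2). Transaldolase (peg.1773) fell by 0.71 ± 0.07 and transketolase (peg.1236) by 0.49 ± 0.07 (log2) in the authors' deposited table. Genes of the tricarboxylic acid cycle were lower in 13 of 23 and higher in 4, the same adjusted over the list alone (adjusted p = 0.0150, and adjusted p = 0.0919 with a correlation of 0.05), a call also lost with log2 fold changes in place of z (adjusted p = 0.179). Malate dehydrogenase (peg.2412) fell by 0.64 ± 0.07 in the authors' deposited table and an aconitase (peg.4245) rose by 0.78 ± 0.08. In the mutant on phenanthrene, 11 of these 23 genes were lower than in wild type and 1 higher (adjusted p = 0.281), and on glucose 5 were lower and 2 higher (adjusted p = 0.870). The glucose pathway list had 14 lower and 6 higher of 32 in the mutant on phenanthrene (adjusted p = 0.321), and 11 lower and 3 higher on glucose (adjusted p = 0.223). Glyoxylate shunt, anaplerosis and gluconeogenesis genes were lower in 6 of 11 and higher in 2 in wild type on phenanthrene (adjusted p = 0.264). Their list includes pyruvate carboxylase (peg.1953, 1.85 ± 0.09 in the authors' deposited table), which lies in the aromatic block. Pyruvate,phosphate dikinase (peg.1930) and a gene annotated as tartrate dehydrogenase and D-malic enzyme (peg.1933) have numbers in the same block. They rose by 2.97 and 2.84 (log2) in the authors' deposited table. Genes of fatty acid oxidation, propionate and polyhydroxyalkanoates were higher in 10 of 55 and lower in 3 (adjusted p = 0.381), with 2-methylcitrate synthase (peg.4243) up by 0.85 ± 0.07 in the authors' deposited table.

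Of the other lists in wild type, oxidative phosphorylation genes were higher in 15 of 45 and lower in 15, or 18 and 15 adjusted over the list alone, a list called higher (adjusted p = 0.00196, and adjusted p = 0.0626 with a correlation of 0.05). With ranks the call was lost (adjusted p = 0.445), and without the 4 cbb3 genes on the list its direction turned to lower (adjusted p = 0.759), so the call rests on these genes. TonB-dependent receptor genes were lower in 19 of 70 and higher in 3 (adjusted p = 0.0150, and adjusted p = 0.184 with a correlation of 0.05). Chaperone genes were lower in 12 of 30 and higher in 5 (adjusted p = 0.00709, and adjusted p = 0.0769 with a correlation of 0.05), a call lost with ranks (adjusted p = 0.141). For both, the counts adjusted over the list alone were the same and the list median turned positive under equal totals, with 9 higher and 14 lower TonB-dependent receptor genes and 9 higher and 9 lower chaperone genes. Genes of the trehalose, glycogen and ectoine list were higher in 10 of 24 and lower in 4, or 11 and 4 adjusted over the list alone (adjusted p = 0.0316, and adjusted p = 0.146 with a correlation of 0.05), a call lost with ranks (adjusted p = 0.141) and with log2 fold changes (adjusted p = 0.229). Their mean log2 fold change was 0.21 and their median -0.01, so mean and median differ in sign, and the median turned positive under equal totals.

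Other list results missed the threshold. Where 3 values are given, they are in the order mutant on glucose, mutant on phenanthrene, and phenanthrene over glucose in wild type. Oxidative stress genes had 15, 16 and 11 members higher and 10, 19 and 13 lower (adjusted p = 0.230, 0.853 and 0.808). Efflux pump genes had 11, 21 and 14 higher and 21, 19 and 16 lower (adjusted p = 0.468, 0.260 and 0.744). Sulfur assimilation genes had 0, 6 and 0 higher and 4, 7 and 6 lower (adjusted p = 0.398, 0.898 and 0.167), and nitrogen assimilation genes 4, 3 and 3 higher and 7, 8 and 7 lower (adjusted p = 0.468, 0.760 and 0.685). For these 4 lists the median in wild type changed sign under equal totals. Mobile element genes had 15, 19 and 13 higher and 3, 6 and 4 lower (adjusted p = 0.223, 0.147 and 0.427). Genes of 2-component systems and sigma factors had 42, 40 and 25 higher and 17, 33 and 11 lower (adjusted p = 0.179, 0.572 and 0.482), called higher on glucose among genes with a mean value of at least 50 (adjusted p = 0.0368). In the mutant, glyoxylate shunt genes had 1 member higher and 2 lower on glucose (adjusted p = 0.442) and 2 higher and 5 lower on phenanthrene (adjusted p = 0.281). The fatty acid, propionate and polyhydroxyalkanoate list had 5 higher and 9 lower on glucose (adjusted p = 0.588) and 3 higher and 11 lower on phenanthrene (adjusted p = 0.700). Upper pathway genes in the mutant on phenanthrene had 3 higher and 15 lower (adjusted p = 0.112), and conjugation genes 22 higher and 8 lower (adjusted p = 0.112). On phenanthrene the conjugation list was called higher with ranks (adjusted p = 0.00379) and with log2 fold changes (adjusted p = 0.00974), and the TonB-dependent receptor and mobile element lists with ranks (adjusted p = 0.0429 each). Conjugation genes in wild type had 13 higher and 8 lower (adjusted p = 0.747), and flagellar genes 13 higher and 28 lower (adjusted p = 0.0633), a list called lower with ranks (adjusted p = 0.0291). Under equal totals the larger count in wild type changed side for flagellar genes (16 higher and 13 lower), oxidative stress genes (18 and 8), efflux pump genes (22 and 8) and nitrogen assimilation genes (8 and 5). TonB-dependent receptor genes in the mutant had 16 higher and 19 lower on glucose (adjusted p = 0.398) and 30 higher and 12 lower on phenanthrene (adjusted p = 0.260). Iron uptake genes had 8 higher and 10 lower on glucose (adjusted p = 0.668) and 13 higher and 5 lower on phenanthrene (adjusted p = 0.321). In the mutant on glucose, flagellar genes had 8 higher and 21 lower (adjusted p = 0.179), oxidative phosphorylation genes 12 higher and 10 lower (adjusted p = 0.805) and chaperone genes 3 higher and 8 lower (adjusted p = 0.468). Ribosomal protein genes in the mutant on phenanthrene had 11 higher and 14 lower (adjusted p = 0.891). Mean, median and test differed in sign for several lists that missed the threshold, such as the sulfur list in the mutant on phenanthrene (median 0.06, mean z negative) and the glyoxylate list in wild type (median -0.24, mean 0.22).

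**Figure D2:**
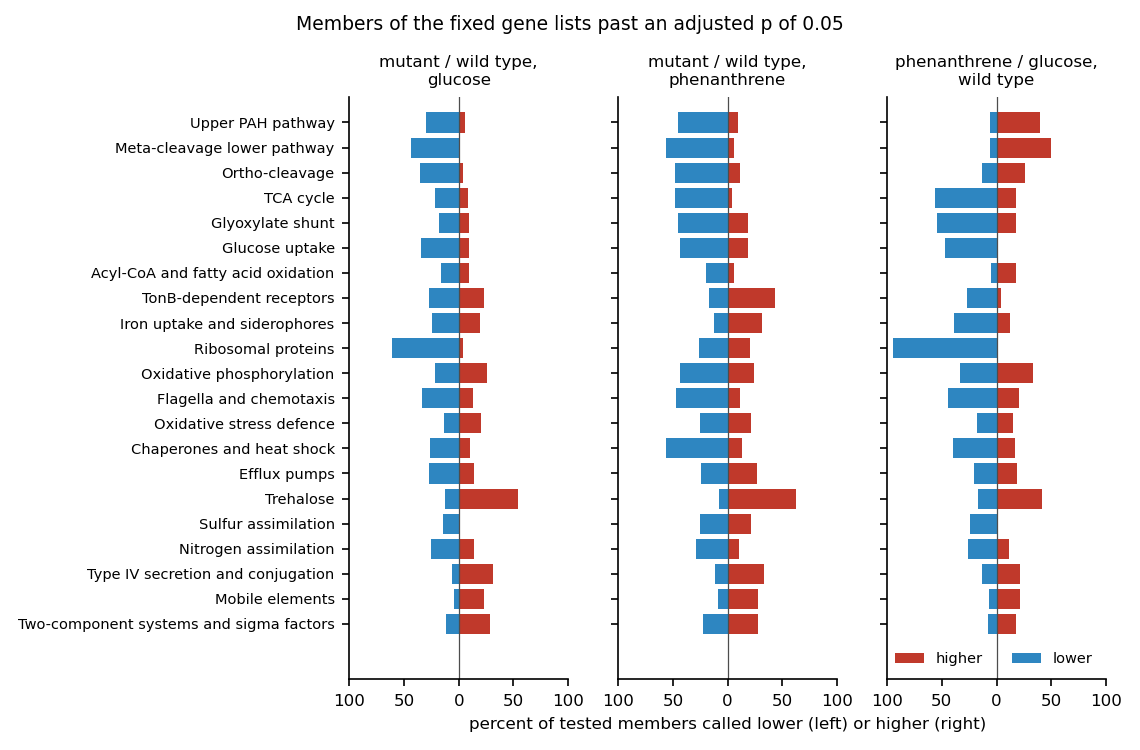
Percent of tested members (horizontal axis) of 21 gene lists (vertical axis) that passed an adjusted p of 0.05 in the authors' deposited tables, lower to the left and higher to the right, for 3 comparisons. Ribosomal protein genes have 51 of 54 members lower on phenanthrene in wild type, and the trehalose, glycogen and ectoine list has 13 and 15 of 24 members higher in the mutant.

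For phenanthrene over glucose in the mutant there is no authors' table here, so group values were put on the scale of the wild-type table and compared without a test. Among 3024 genes with a value of at least 50 in some group, 110 were at least 2-fold higher on phenanthrene in the mutant and 27 lower, and 125 and 40 in wild type. The aromatic block from peg.1926 to peg.1997 was higher on phenanthrene in the mutant too, by a median of 1.94 (log2), or 3.85-fold. The large dioxygenase subunit (peg.1926) had values of 99.0 on glucose and 1080 on phenanthrene in the mutant, and 200.0 and 1282 in wild type. The cbb3 genes differed less in the mutant, by a median of 1.71 (log2), or 3.26-fold. The alcohol dehydrogenase genes had a median of -0.29 and the fructose genes of 0.10 in the mutant, where their values were low on both carbon sources.

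**Figure D3:**
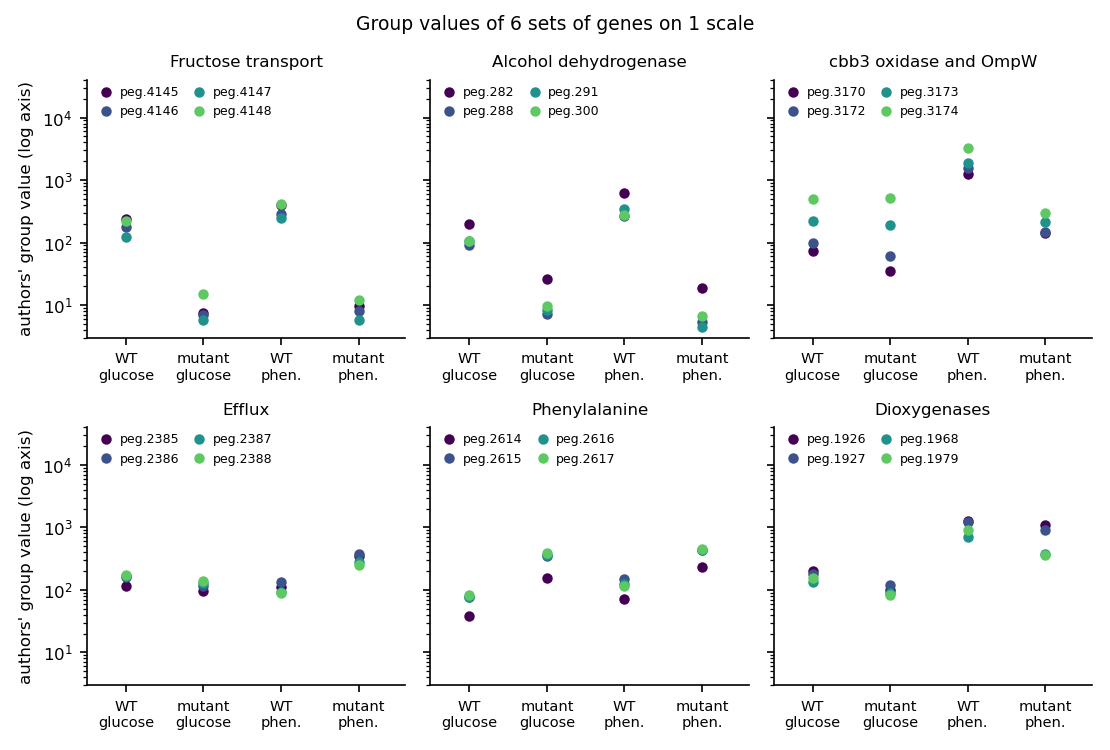
The authors' pooled values (vertical log axis, on the scale of the wild-type table) of 4 genes in each of 6 sets, in the 4 groups named on the horizontal axis, 1 point per gene and group, with no error because the tables give none. CcoO (peg.3172) has values of 97.4, 60.5, 1567 and 146 in the order of the groups, and outer membrane protein W (peg.3174) of 491, 526, 3244 and 292.

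The effect of the mutation was then compared between the carbon sources. Genes of the cbb3 oxidase were lowered far more by the mutation on phenanthrene than on glucose, and a tripartite efflux system was lower in the mutant on glucose and higher on phenanthrene. The difference was tested as the difference of the log2 fold changes, phenanthrene minus glucose, with a normal test on the implied SEs. This test was added after the tables were seen. Of 5998 genes, 531 passed an adjusted p of 0.05, 207 with a positive and 324 with a negative difference, and 87 differed at least 2-fold, 27 positive and 60 negative. The cbb3 run had the most negative differences among the named genes: outer membrane protein W (peg.3174, -3.57), CcoQ (peg.3171, -3.02 ± 0.44), CcoN (peg.3173, -2.92 ± 0.23) and CcoO (peg.3172, -2.73 ± 0.17). All 10 tested genes of the run passed, with a median of -2.26. The ADP-forming acetyl-CoA synthetase (peg.1512) had a difference of -2.73 ± 0.23: its value was higher in the mutant on glucose and lower on phenanthrene. The efflux genes peg.2385 to peg.2388 went the other way, with differences of 1.92 ± 0.14, 1.98 ± 0.13, 1.93 ± 0.12 and 1.83 ± 0.13, lower in the mutant on glucose and higher on phenanthrene. The cation efflux protein CzcD (peg.3690) had a difference of 1.31 ± 0.10. In the alcohol dehydrogenase run 10 of 19 genes had a negative difference that passed (median -1.63), and in the fructose run 2 of 4. Implied errors of the alcohol dehydrogenase run were 3.29 times those of genes of similar wild-type value on glucose, and 1.64 times on phenanthrene. Low mutant values may raise these ratios. In the aromatic block 6 of 72 genes differed positively and 12 negatively. The difference for acetyl-CoA hydrolase (peg.4899) was -0.32 and missed the threshold, in a test that rests on upper bounds of its errors and so does not show that the effects were equal. With a t distribution in place of the normal one to read the p-values, 1683 genes passed. That reading departs from the Wald test assumed for the implied SEs. It makes the errors of genes with small p-values far smaller, so this count does not check the 531.

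In the list test on these differences 8 lists passed an adjusted p of 0.05. Oxidative phosphorylation genes had 13 negative and 2 positive differences of 46 (adjusted p = 7.74e-07, and adjusted p = 0.00331 with a correlation of 0.05). Flagellar genes had 14 negative and 1 positive of 63, or 23 and 1 adjusted over the list alone (adjusted p = 1.05e-05, and adjusted p = 0.0136 with a correlation of 0.05). Chaperone genes had 8 negative and 0 positive of 30, or 10 and 0 adjusted over the list alone (adjusted p = 1.78e-04, and adjusted p = 0.0136 with a correlation of 0.05), among them ClpB (peg.2269) at -1.46. Ribosomal protein genes had 8 positive and 0 negative of 54, or 11 and 0 adjusted over the list alone (adjusted p = 1.88e-07, and adjusted p = 0.00331 with a correlation of 0.05). Efflux pump genes had 14 positive and 5 negative of 77, or 14 and 7 adjusted over the list alone (adjusted p = 3.41e-04, and adjusted p = 0.0680 with a correlation of 0.05). TonB-dependent receptor genes had 11 positive and 2 negative of 70, or 13 and 2 adjusted over the list alone (adjusted p = 5.42e-04, and adjusted p = 0.0680 with a correlation of 0.05). Iron uptake genes had 9 positive and 1 negative of 41 (adjusted p = 0.0151, and adjusted p = 0.165 with a correlation of 0.05), and tricarboxylic acid cycle genes 4 negative and 0 positive of 23 (adjusted p = 0.0438, and adjusted p = 0.178 with a correlation of 0.05). Fumarase (peg.818), of the last list, had a difference of -1.02. Among genes with a mean value of at least 50 the calls for TonB-dependent receptors, iron uptake and the tricarboxylic acid cycle were lost (adjusted p = 0.362, 0.902 and 0.260). With log2 fold changes in place of z the calls for chaperones and the tricarboxylic acid cycle were lost. With ranks those for iron uptake and efflux pumps were lost, and under equal totals that for the tricarboxylic acid cycle.

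Over 5998 genes the mutation effects on glucose and on phenanthrene had a Pearson r of 0.744 and a Spearman rho of 0.708, across genes, which are not independent replicates. These 2 comparisons share no library. Of 1702 genes called in both, 97.6% changed in the same direction, 848 higher in both (268 for independent lists) and 813 lower in both (271 for independent lists). Only 41 genes were called with opposite signs, among them the 4 efflux genes and 2-methylcitrate synthase (peg.4243), at 0.27 ± 0.08 on glucose and -0.51 ± 0.06 on phenanthrene in the authors' deposited tables.

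**Figure D4:**
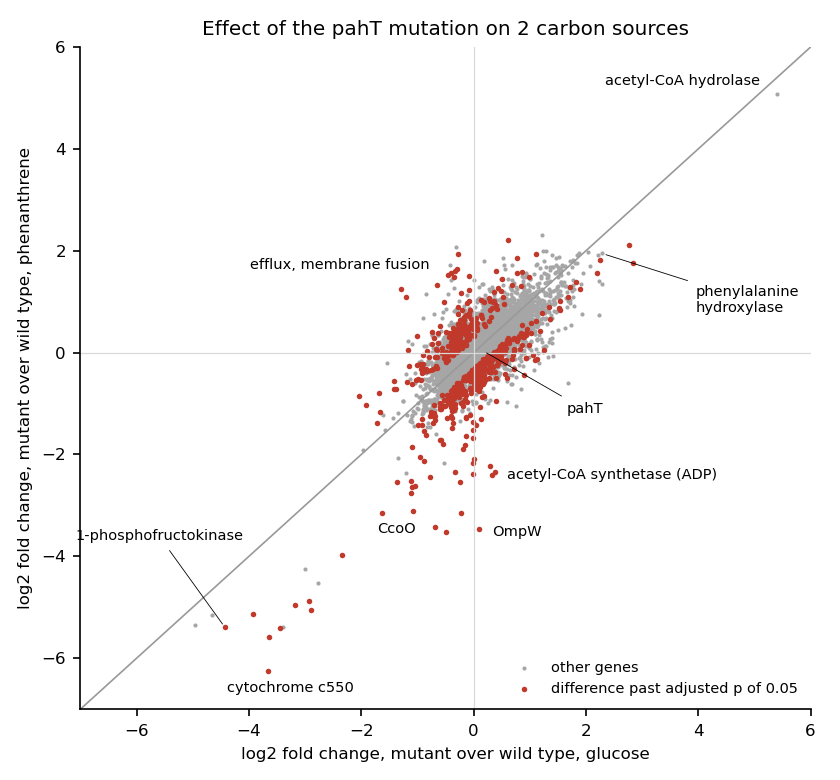
Log2 fold change of the mutant over wild type on phenanthrene (vertical axis) against that on glucose (horizontal axis) for 5998 genes in the authors' deposited tables, with the line of equal effects. Red points are the 531 genes whose effects differed past an adjusted p of 0.05; the cbb3 genes lie below the line and the efflux genes above it.

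The carbon source effect in wild type shares the wild-type libraries of 1 carbon source with each mutation effect. Against the mutation effect on glucose its r across genes was 0.209 and rho 0.391. Simulated unchanged groups gave an r of 0.499, and the covariance was 0.0551 against 0.0223 simulated, a difference of 0.0328. Of 1157 genes called in both, 79.3% had the same direction. Both were higher for 432 genes (183 for independent lists) and lower for 486 (207 for independent lists). Against the mutation effect on phenanthrene the r was -0.148 and rho 0.0415, with a simulated r of -0.493 and a covariance of -0.0442 against -0.0180 simulated, a difference of -0.0262. Of 1308 genes called in both, 57.6% had the same direction: 348 were higher in both (228 for independent lists) and 405 lower (279 for independent lists), while 337 were higher on phenanthrene and lower in the mutant (243 for independent lists) and 218 the reverse (263 for independent lists). The simulations gave 0 genes called in both. Their groups were unchanged, so they cannot show how shared libraries affect joint calls among genes that change. The wild-type libraries cannot be split here, so part of these values may come from the shared libraries.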

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

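All tests of explanations here were chosen after the results were seen, except the test of oxygen limitation. That test was written before its result was seen, but it left out regions picked after their values were seen. The results come from the test of the difference between the mutation effects on phenanthrene and on glucose, in which 531 genes passed an adjusted p of 0.05.

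Among the named genes the difference (log2) was -3.57 for outer membrane protein W (peg.3174), -3.02 for CcoQ (peg.3171), -2.92 for CcoN (peg.3173) and -2.73 for CcoO (peg.3172). It was also -2.73 for the ADP-forming acetyl-CoA synthetase (peg.1512). Positive differences were 1.98 for peg.2386, 1.93 for peg.2387, 1.92 for peg.2385 and 1.83 for peg.2388, the efflux system and its neighbouring regulator, and 1.31 for CzcD (peg.3690). Beyond these, 93 other named genes passed. The lists that passed were the tricarboxylic acid cycle (adjusted p = 0.0438, negative), TonB-dependent receptors (adjusted p = 5.42e-04, positive), iron uptake (adjusted p = 0.0151, positive), ribosomal proteins (adjusted p = 1.88e-07, positive), oxidative phosphorylation (adjusted p = 7.74e-07, negative), flagella (adjusted p = 1.05e-05, negative), chaperones (adjusted p = 1.78e-04, negative) and efflux pumps (adjusted p = 3.41e-04, positive). With a correlation of 0.05 the calls for the tricarboxylic acid cycle, TonB-dependent receptors, iron uptake and efflux pumps were lost (adjusted p = 0.178, 0.0680, 0.165 and 0.0680).

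The cbb3 oxidase genes were far higher on phenanthrene in wild type and far lower in the mutant on phenanthrene, with a median difference of -2.26. Reads shared with another annotated cytochrome c oxidase would need that gene to fall with the run, but the 6 such genes outside it lay between -0.0452 and 1.12 in the mutant on phenanthrene in the authors' deposited table, which argues against it; reads shared with genes under other product names were not tested. Oxygen limitation of the wild-type phenanthrene cultures may also raise these genes, and 6 genes of a low-oxygen list were examined. The list left out the run, numbers close to it, the alcohol dehydrogenase run and genes numbered around the ADP-forming acetyl-CoA synthetase (peg.1512). These regions were picked after their values were seen, and the list does not speak for them. The 6 genes had a median of 0.0371 in the mutant over wild type on phenanthrene (95% interval -0.63 to 0.25). On phenanthrene over glucose in wild type the median was -0.16 (-0.43 to 0.86). Both intervals come from a bootstrap over the 6 genes and do not measure the spread between libraries. Members went both ways, so oxygen limitation cannot be told apart. Of the 6, only the haemoglobin-like protein HbO was called in both of the authors' deposited tables in the directions of the run, and an effect of the mutation itself also stays open, untested.

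The alcohol dehydrogenase and fructose genes were low in the mutant on both carbon sources, where a loss of these genes from the mutant genome is 1 candidate explanation. If residual values came from wild-type reads, each run would show a single fold change. In the alcohol dehydrogenase run fold changes ranged from -6.26 to -0.45 on phenanthrene (Q = 2780 on 18 degrees of freedom). Its limits were drawn after the values were seen and take in genes that fell less. Among these are peg.286, at 60.0 in the mutant and 81.6 in wild type, peg.284 (31.3 and 84.7) and peg.287 (25.2 and 130). This Q therefore bears only on loss of all 19 genes, and does not bear on loss of the run without such genes. In the fructose run on glucose fold changes ranged from -4.97 to -3.93 (Q = 27.5 on 3 degrees of freedom). The fructose range on glucose argues against loss of that whole run with wild-type reads as the only residue. Loss of part of a run and residual reads from similar genes were not tested. On phenanthrene the fructose run leaves a single fold change open (Q = 2.66 on 3 degrees of freedom), with errors that are upper bounds. The implied errors of the alcohol dehydrogenase run were compared with those of genes of similar value in the wild-type group. In the tables with the wild-type glucose libraries they were 3.29 (mutant over wild type) and 3.50 (wild type only) times as large. Low mutant values may raise the 3.29, but the 3.50 involves no mutant library. In the phenanthrene table the ratio was 1.64, over 16 genes, without those with p listed as 0. The wild-type glucose libraries may therefore differ from each other. The run was also lower by -3.97 in the table without them, which argues against that as the whole cause. A second change in the mutant strain and an effect of pahT stay open, untested.

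The value of the gene taken as pahT was not lower in the mutant, and libraries with a wrong genotype label are 1 candidate explanation. A single wild-type library among 3 mutant ones would keep lower genes above a 3-fold decrease, and a single mutant library among wild-type ones would keep higher genes below a 3-fold increase, but at least 12 genes lay beyond 3-fold by over 2 implied errors in each direction of both tables, which argues against single wrong labels. A swap of whole groups is not excluded, since the directions rest on the labels. An insertion that leaves part of the gene transcribed, and a number that does not stand for orf1998, stay open, untested.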

How the results depend on the processing

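Scaling by equal column totals, the t distribution, leaving out genes with p listed as 0, the list test settings and leaving out the cbb3 run were chosen after seeing the data. No paired analysis was possible because the tables hold no value per library. For the same reason leaving out each replicate, a replicate block, other splits of the samples, TMM, RLE and upper quartile factors, edgeR, DESeq2, a fit of all 12 libraries, fry and an estimated correlation were not run, and nothing is known here of how far single libraries decide a value. The unknown depth limits what a missed threshold means, above all for genes with low values.

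Counts of changed genes stayed within 1.5 times their value under equal totals (2240 on glucose, 2884 on phenanthrene, 2212 in wild type, 509 for the difference) and an adjusted p of 0.01 (1638, 2309 and 1573), but not for the difference at 0.01 (326). The wild-type genes differ more than their number: under equal totals 1510 of 2036 were shared, and higher and lower genes went from 947 and 1089 to 1649 and 563, since every log2 fold change rose by 0.157. With a mean value of at least 50, fewer genes were tested: 1402 were called on glucose and 1933 on phenanthrene, and 1505 in wild type and 469 for the difference stayed within 1.5 times. At least 2-fold changes left 328, 411, 230 and 87 genes. A t distribution gave 1683 genes for the difference, through far smaller errors for genes with small p-values, so this count is no check. Leaving out genes with p listed as 0 gave 523. Without a filter 240 genes changed at least 2-fold in the mutant's values against 137, since low values enter. Pseudocounts of 0.1, 1 and 10 gave 137, 135 and 115.

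Among genes with a mean value of at least 50, the carbon source effect in wild type and the mutation effect on phenanthrene had an r of -0.286 and a rho of -0.0173, reversed from 0.0415, and the carbon source effect and the mutation effect on glucose an r of 0.104; the cause was not tested. Lists called with a correlation of 0.05 numbered 1 against 6 on glucose, 5 against 11 in wild type and 4 against 8 for the difference, and 5 for the difference among genes with a mean value of at least 50. There the iron uptake list's mean z for the difference went from 0.77 to -0.41, its direction against other genes staying positive (adjusted p = 0.902). For the difference 7 lists were called under equal totals, without the tricarboxylic acid cycle (adjusted p = 0.0549), 6 with ranks, without iron uptake and efflux pumps (adjusted p = 0.0797 and 0.136), and 6 with log2 fold changes in place of z, without the tricarboxylic acid cycle and chaperones (adjusted p = 0.380 and 0.0559). In wild type ranks kept 7 of 11 list calls, losing ortho-cleavage, oxidative phosphorylation, chaperones and trehalose, and gained flagella (adjusted p = 0.0291); log2 fold changes kept 9, losing the tricarboxylic acid cycle and trehalose. On phenanthrene ranks kept 5 of 6, losing oxidative phosphorylation, and gained conjugation (adjusted p = 0.00379), TonB-dependent receptors and mobile elements (adjusted p = 0.0429 each), and log2 fold changes gained conjugation (adjusted p = 0.00974). Without the cbb3 run the oxidative phosphorylation list reversed in wild type (mean z -0.180, adjusted p = 0.759) and missed the threshold on phenanthrene (adjusted p = 0.252), since these genes carry both calls, while for the difference it passed (adjusted p = 0.0306). The conjugation list on glucose reversed among genes with a mean value of at least 50 (mean z -1.76, adjusted p = 0.503). Under equal totals all named genes kept their call and direction on glucose (101), on phenanthrene (102) and for the difference (10), as did 95 in wild type; ribosomal protein L31 (peg.957) and TraA (peg.2004) lost it (adjusted p = 0.0751 and 0.0905).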

Other observations

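The strain has a pair of GroES and GroEL gene sets that moved in opposite directions in the mutant on phenanthrene. In the authors' deposited table GroEL (peg.38), a chaperonin that folds proteins, was lower by -0.97 ± 0.06 and GroES (peg.37) by -0.90 ± 0.07. The other set was higher in the same authors' deposited table, GroEL (peg.5695) by 0.93 ± 0.06 and GroES (peg.5696) by 0.70 ± 0.08. Values on glucose, on the scale of the wild-type table, lay in the same directions. GroEL peg.38 had 4096 in the mutant and 5320 in wild type, and GroEL peg.5695 had 1644 and 1050. GroES peg.37 had 4912 in the mutant and 6226 in wild type, and GroES peg.5696 had 1970 and 1395. On phenanthrene over glucose in wild type both sets were lower in the authors' deposited table, peg.38 by -1.18 ± 0.08 and peg.5695 by -2.24 ± 0.08. A pair of catalases, which break down hydrogen peroxide, were higher in the mutant on phenanthrene in the authors' deposited table, peg.5710 by 1.56 ± 0.10 and peg.5819 by 1.17 ± 0.12. On glucose peg.5710 was higher by 1.67 ± 0.11 in the authors' deposited table.

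Sulfate adenylyltransferase, the enzyme that activates sulfate, was lower in the mutant on glucose in the authors' deposited table (peg.1707, -0.79 ± 0.10, and peg.1708, -0.85 ± 0.10). Glutamate synthase genes moved in opposite directions there in the authors' deposited table: the NADPH enzyme's large chain (peg.3224) was lower by -0.64 ± 0.08 and a ferredoxin-dependent enzyme (peg.72) higher by 1.22 ± 0.10. TonB-dependent receptors went both ways on glucose in the authors' deposited table, peg.5237 by -1.72 ± 0.09 and peg.5576 by 1.54 ± 0.11. Among the most abundant transcripts, ribosomal protein L7/L12 (peg.32) was lower on phenanthrene in wild type (-0.50 ± 0.08) in the authors' deposited table, as were the DNA-binding protein HU-beta (peg.937, -0.45 ± 0.08) and the hypothetical protein peg.3003 (-0.32 ± 0.07). Outer membrane protein A (peg.178) was higher in the mutant on phenanthrene in the authors' deposited table (0.56 ± 0.05).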
